A study of Homo sapiens with 6 samples.

How the data were processed

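Total RNA of PC3 cells, an established human prostate cancer line, was hybridised to 6 Affymetrix HG-U133 Plus 2.0 arrays after 72 h with scrambled siRNA, VEGF-C siRNA or NRP-2 siRNA, with 2 arrays in each of the 3 groups. Per the labels' protocols, the cells grew in RPMI medium with 10% serum, the siRNAs were pools, and biotin-labelled material was made from 6 ug of total RNA. The same labels name Santa Cruz Biotechnology as the supplier of the NRP-2 siRNA and Dharmacon as that of the VEGF-C siRNA, so the target and the supplier of an siRNA changed together. Groups and replicate numbers were taken from the sample labels.

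The authors deposited log2 values per probe set, made with Partek and GCRMA per the submitters' processing notes; versions and settings are not given in the sources used here. GCRMA corrects the background of each probe from its sequence, normalizes the arrays to each other and summarises the probes of a set. The deposited log2 values ran from 0.82 to 16.32, and the medians of the arrays spread over 0.07. Values near the floor are compressed, so that a fold change of a dim gene is understated. Detection calls and scanner files were not used here, so no gene is called present or absent, and the number of arrays limits the precision.

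Of the 54675 probe sets, 62 were controls, 41091 had 1 gene in the platform annotation of 2016, 1801 had several and 11721 had none named. No symbol needed an update through its Entrez identifier (0 changed), and 19775 genes were named. Probe sets with 1 gene and a mean of at least log2 4 over the 6 arrays were kept (19946), and each of the 11131 genes left was represented by its probe set with the highest mean. Probe sets without 1 gene name were tested separately and are not named.

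Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a fit of all 6 arrays, which share a spread with 3 residual degrees of freedom, a prior of 2.46 degrees of freedom and a prior standard deviation of 0.165. The 3 comparisons were VEGF-C siRNA against scrambled siRNA, NRP-2 siRNA against scrambled siRNA, and NRP-2 siRNA against VEGF-C siRNA. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 11131 genes. The same fit gave p-values adjusted over each gene list alone, and a gene is said to have risen or fallen when that value was under 0.05. These values were not adjusted across lists or comparisons, so how easily a gene passes depends on the size and the other members of its list. Unless stated otherwise, a change is a log2 difference of means with its standard error (SE), and a level is a mean of deposited log2 values with the standard deviation (SD) of 2 arrays.

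The 26 gene lists were written from general knowledge and hold 817 genes, of which 680 were measured past the filter and 63 had no named probe set here. Lists with at least 5 measured members (23) were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all 69 tests of lists and comparisons. The test was repeated with an inter-gene correlation estimated from the residuals and with fry, which asks whether the genes of a list move on balance in a common direction and does not compare them with other genes.

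The targeted genes VEGFC and NRP2, and LAMP2 and WDFY1, were to be named whatever their values. For each comparison the rule took called genes with the largest changes and, where too few were called, the 5 genes with the smallest unadjusted p in each direction, given as not past the threshold. From each list up to 4 members with the smallest p over the comparisons against scrambled siRNA were named. Members past the threshold over their list alone are also named. The design, the lists, the naming rule and most alternatives were fixed before the data were examined.

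Comparisons against scrambled siRNA share its 2 arrays. Correlation, covariance and same-sign share of their changes are therefore given beside 100 simulated sets of unchanged groups against the same controls. These used the residual standard deviation of each gene. A simulated correlation near 0.50 follows from sharing controls between groups of equal size. Counts shared by both are given beside 20 simulated sets with variances drawn from limma's prior, and beside the overlap of independent lists.

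The procedure was tested on simulated data for the comparison of VEGF-C siRNA with scrambled siRNA, with 200 of 11131 genes changed in each of 20 draws. It recovered 34.7% of genes changed 2-fold, 85.8% of those changed 4-fold and 94.3% of those changed 8-fold, and 5.295% of its calls were false. The variances were drawn from limma's prior. On the real arrays VEGFC, 15.4-fold lower with its siRNA, was not called (limma's adjusted p = 0.204), so these shares may not hold there. A shifted list had an unadjusted camera p under 0.05 in 20 draws. The same list, unshifted between NRP-2 and scrambled siRNA, had one in 2 draws. Because the simulated genes varied independently, these draws do not test camera on lists whose members move together.

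Alternatives covered the filter on low values, the normalization, the treatment of several probe sets of a gene, the moderation of the variance, the arrays in the fit, the replicate number as a block, each array left out in turn, the threshold and the list test. The mean of the G2 and mitosis genes as a covariate was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.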

Results

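Gene expression was measured in PC3 prostate cancer cells 72 h after transfection with an siRNA pool against VEGFC, an siRNA pool against NRP2 or a scrambled siRNA. Each group had 2 arrays with 54675 probe sets. VEGFC encodes a growth factor of lymphatic vessels, and NRP2 encodes neuropilin-2, a co-receptor for VEGF-C and for class 3 semaphorins. The title of the series names autophagy, the degradation of cell contents in lysosomes, as the process under study, and the comparisons ask which transcripts change when the ligand or its co-receptor is depleted. The medians of the 6 arrays lay within 0.07 of each other on the log2 scale. The labels list the arrays of a group as separate samples without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

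Each targeted transcript was lower in the cells that received its siRNA. VEGFC fell from log2 11.81 ± 0.01 (SD, n = 2) with scrambled siRNA to 7.86 ± 0.84 with VEGF-C siRNA, a change of -3.95 (SE 0.39) or 15.4-fold, and stood at 11.83 ± 0.23 with NRP-2 siRNA. NRP2 fell from 4.85 ± 0.11 to 3.11 ± 0.43 with NRP-2 siRNA, a measured change of -1.74 (SE 0.26), and stood at 5.76 ± 0.35 with VEGF-C siRNA (+0.91, SE 0.26). Adjusted over the list of VEGF, neuropilin, semaphorin and plexin genes alone, p was 0.00179 for VEGFC, 0.0165 for NRP2 with its own siRNA and 0.0498 for NRP2 with VEGF-C siRNA. Over all genes tested, limma's adjusted p was 0.204 for VEGFC and 0.213 for NRP2 with its own siRNA. Of the 11 NRP2 probe sets, 1 had a mean of at least log2 4, so NRP2 was measured close to the floor. With NRP-2 siRNA it stood near the medians of those arrays (3.01 and 3.04), and the size of its fall is not known from these values. A second NRP2 probe set, with a mean under log2 4, gave +2.13 with VEGF-C siRNA and -0.52 with NRP-2 siRNA. The call of VEGFC was kept without any of the 6 arrays. That of NRP2 with its own siRNA was lost without scrambled array 1 (-1.81, adjusted p = 0.0985 over the list alone) or scrambled array 2 (-1.66, 0.139), with no low-value filter (0.06) and with the mean of the G2 and mitosis genes as a covariate, a model chosen after seeing the data (-1.74, SE 0.34, 0.0679). That of NRP2 with VEGF-C siRNA was lost without scrambled array 1 (+0.84, 0.239), scrambled array 2 (+0.99, 0.169), VEGF-C array 1 (+1.16, 0.0727) or VEGF-C array 2 (+0.67, 0.274), with no low-value filter (0.114), for the mean of all probe sets (0.0567) and with the covariate (+0.91, SE 0.38, 0.19).

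WDFY1, an endosomal protein that binds phosphatidylinositol 3-phosphate, was higher with both siRNAs. It rose from log2 10.26 ± 0.23 (SD, n = 2) to 11.72 ± 0.18 with VEGF-C siRNA (+1.45, SE 0.18) and to 11.93 ± 0.15 with NRP-2 siRNA (+1.67, SE 0.18), with an adjusted p of 0.0123 and 0.00603 over the list of endosome trafficking and phosphoinositide effectors alone. Its second probe set gave +1.42 and +1.41. LAMP2, a glycoprotein of the lysosomal membrane, rose with NRP-2 siRNA from 12.39 ± 0.27 to 13.89 ± 0.15 (2.83-fold, adjusted p = 0.0109 over the list of lysosomal proteins alone) and stood at 13.43 ± 0.16 with VEGF-C siRNA (+1.05, adjusted p = 0.0699 over the list alone). The 4 probe sets of LAMP2 disagreed, and these values come from the brightest. The others gave +0.12, +0.04 and +0.02 with VEGF-C siRNA and, in the same order, +0.11, +0.10 and +1.89 with NRP-2 siRNA. The call of WDFY1 with VEGF-C siRNA was lost without scrambled array 1 (+1.29, adjusted p = 0.109 over the list alone) or VEGF-C array 1 (+1.32, 0.118). With NRP-2 siRNA it was lost without scrambled array 1 (+1.51, 0.0574) or NRP-2 array 1 (+1.57, 0.0587), and that of LAMP2 without scrambled array 1 (+1.31, 0.0872) or NRP-2 array 1 (+1.39, 0.0831). With the covariate WDFY1 was 2.82-fold higher with VEGF-C siRNA (2.74-fold without it) and lost its call (0.0868) as the SE went from 0.18 to 0.26. For the mean of all probe sets LAMP2 was at +0.90 (0.0489) with NRP-2 siRNA and +0.31 with VEGF-C siRNA.

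**Figure D1:**
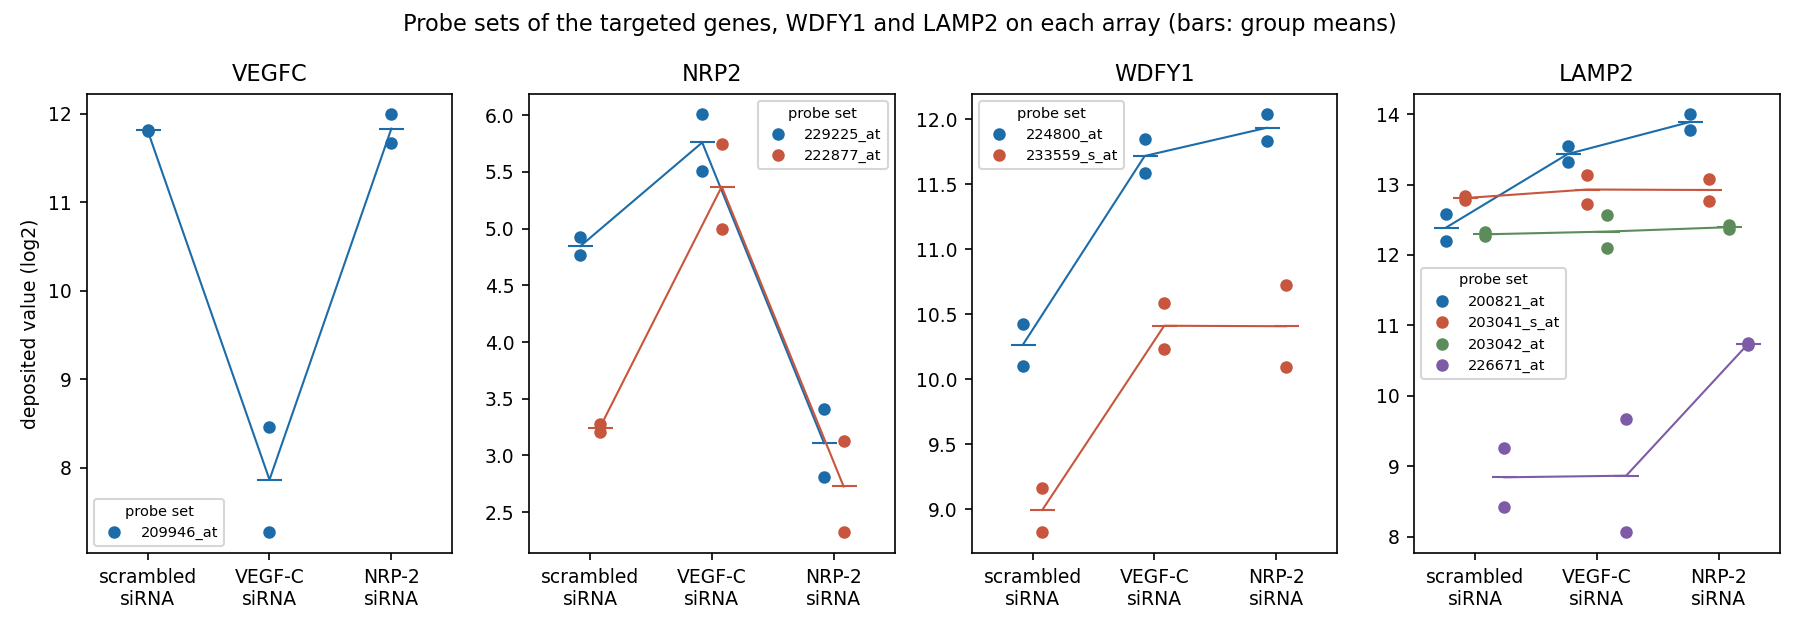
Deposited log2 values (vertical axis) of the probe sets of VEGFC, NRP2, WDFY1 and LAMP2 on each of the 6 arrays, by siRNA group (horizontal axis), with a point for each array, a bar at each group mean and lines joining the means. VEGFC is lowest with VEGF-C siRNA and NRP2 with NRP-2 siRNA, both WDFY1 probe sets are higher with either siRNA, and the means of 2 LAMP2 probe sets (red and green) lie +0.04 to +0.12 above scrambled siRNA while that of the brightest (blue) is 2.83-fold higher with NRP-2 siRNA.

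VEGF-C siRNA was compared with scrambled siRNA to ask what changed in cells given the siRNA against the ligand. A single pool was used, so effects of depletion on a gene cannot be told from those of the siRNA sequences. Besides VEGFC, the semaphorin genes SEMA3E (-1.97, SE 0.24) and SEMA3C (-0.84, SE 0.16) fell, as did the plexin gene PLXNB1 (-0.80). DICER1, the enzyme that makes small interfering RNAs and microRNAs, fell as well (-1.98, SE 0.32). AKR1C1, an aldo-keto reductase of the NRF2 response, rose (+1.21, SE 0.14), and so did EPG5 (+1.16, SE 0.17), which acts in the fusion of autophagosomes with lysosomes, MTMR6 (+0.86), a phosphoinositide phosphatase, and BIK (+0.89), a pro-apoptotic BCL2 family member. EGF rose (+1.05), and PDGFB (-0.94) and the p53 target ZMAT3 (-0.90) fell.

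The interferon response list shifted up with VEGF-C siRNA by a mean of +0.39, with 43 of 44 members above 0. EPSTI1 (+1.07), OASL (+0.77) and IFIT3 (+0.64) rose over the list alone, and the other 41 members did not pass (adjusted p of the list = 7.63e-10, and adjusted p = 0.949 with an estimated correlation). Without scrambled array 1 the mean was +0.24. The integrated stress and amino acid response list shifted up by +0.33, with 32 of 34 members above 0 and 0 past the list-alone threshold, and its examples were CTH, an enzyme of cysteine synthesis (+1.34), and PPP1R15A, which reverses the block on translation (+0.75). Inflammatory cytokines and NF-kB targets shifted by +0.80, with 0 of 20 members past the list-alone threshold and the neutrophil chemokines CXCL3 at +2.60 and CXCL5 at +2.19, CCL20 at +2.17 and the decoy receptor gene TNFRSF11B at -1.45. Of these 20, 10 passed as higher and 1 as lower without either NRP-2 array, and 3 as higher for the mean of all probe sets. With the G2 and mitosis mean as a covariate CXCL3 was at +1.54, CXCL5 at +1.17 and TNFRSF11B at -0.72, and CTH was at +0.89 without scrambled array 2. NRF2 and oxidative stress genes shifted by +0.31, with 1 of 24 members, AKR1C1, risen, and with GCLC at +0.56 and SRXN1 at +0.55. Adjusted p was 6.78e-05, 0.000235 and 0.000344 for these 3 lists, and each had adjusted p = 0.949 with an estimated correlation. G2 and mitosis genes shifted by +1.31 with 38 of 38 above 0, and S phase and DNA replication genes by +0.51 with 29 of 34 above 0 (adjusted p = 1.82e-10 and 0.0128, and adjusted p = 0.949 and 0.953 with an estimated correlation). None of the cell cycle members passed over its list alone (0 of 38 and 0 of 34), among them AURKB (+1.99), UBE2C (+1.59), CENPA (+1.71), CENPE (+1.27) and CDC6 (+1.70). With the replicate number as a block, members of both lists passed as higher, as counted below under the processing alternatives. Without scrambled array 1, which had the higher mean of the scrambled arrays, 35 G2 and mitosis members passed as higher. Without scrambled array 2 AURKB was at +0.99, UBE2C at +0.82, CENPA at +0.72 and CENPE at +0.76. CDC6 was at +0.82 with the G2 and mitosis mean as a covariate.

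Over all 11131 genes, limma called 0 genes with VEGF-C siRNA (lowest adjusted p 0.204). At an unadjusted p under 0.05 there were 1642 genes, 774 higher and 868 lower, where 556.55 would be expected by chance. The genes with the smallest p, not past the threshold over all genes, were KRT75 (+1.43), ANXA1 (+1.23), AKR1C1, WDFY1 and the stress keratin KRT16 (+1.88) among those higher. Among those lower they were VEGFC, the iron exporter SLC40A1 (-1.14), the nuclear receptor corepressor LCOR (-1.28), NAP1L2 (-1.44) and SEMA3E. Of the 18 calls made over a list alone, 4 were kept among 40 without scrambled array 1, 3 among 3 without scrambled array 2, 5 among 7 without VEGF-C array 1, 7 among 8 without VEGF-C array 2, and 15 among 37 without either NRP-2 array. The mean of the G2 and mitosis genes differed by 1.62 between the scrambled arrays, and with that mean as a covariate 3 of the 18 were kept. Among those lost AKR1C1 was then at +1.16 (SE 0.21 in place of 0.14). The call of SEMA3E was kept without any of the 6 arrays, with no low-value filter, for the mean of all probe sets and with the covariate. Those of EPG5, BIK, EGF, PDGFB, ZMAT3, EPSTI1, OASL and IFIT3 were lost without any 1 of the 4 arrays compared, as was that of PLXNA2 (+0.40), and those of IFIT3 (0.0513) and PLXNA2 (0.0526) also without either NRP-2 array. That of MTMR6 was lost without any array but VEGF-C array 2, that of PLXNB1 without scrambled array 2 or either VEGF-C array, those of SEMA3C and DICER1 without either scrambled array, and that of AKR1C1 without scrambled array 2 (0.0722). For the mean of all probe sets the calls of EPG5 (+0.75, adjusted p = 0.147 over the list alone), MTMR6 (+0.68), PLXNA2 (+0.33), EPSTI1 (+0.79), OASL (+0.80), IFIT3 (+0.82) and ZMAT3 (-0.78) were lost, and with no low-value filter those of EGF, PDGFB and ZMAT3. PLXNB1 was at -0.51 with the covariate.

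NRP-2 siRNA was compared with scrambled siRNA to ask what changed in cells given the siRNA against the co-receptor. Here too a single pool was used, and effects of depletion cannot be told from those of the siRNA sequences. Besides NRP2, LAMP2 and WDFY1, the laminin gene LAMC1 (+1.77, SE 0.25) and MTMR6 (+0.88, SE 0.14) rose. The integrin gene ITGA2 fell (-1.72, SE 0.22), as did NPC1, the lysosomal cholesterol transporter (-1.22, SE 0.17), RRAGD, a Rag GTPase that recruits mTORC1 to lysosomes (-0.88), the semaphorin gene SEMA3A (-0.76) and COL1A1 (-0.84). Each passed over its list alone, COL1A1 in a list of fibroblast markers with 3 measured members that had no list test, in which ACTA2 was at +0.41 (+0.19 without scrambled array 1) and COL3A1 at +0.36 (-0.04 without NRP-2 array 2).

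The integrated stress and amino acid response list shifted down with NRP-2 siRNA, with a mean of -0.44 and 33 of 34 members below 0 (adjusted p = 1.76e-07, and 0.949 with an estimated correlation). No member passed over the list alone (0 of 34), with WARS1, a tRNA synthetase, at -0.82 and CTH at -0.82. Without NRP-2 array 1 the mean was -0.18 and WARS1 was at -0.46, and without NRP-2 array 2 the mean was -0.70 and 22 members passed as lower and 1 as higher. The interferon list had a mean of -0.24, with 34 of 44 members below 0 and 0 past the list-alone threshold, IFI44 (-0.81) and OASL (-0.53) among them (adjusted p = 0.00116, and 0.949 with an estimated correlation). Without scrambled array 2 its mean was -0.09 (adjusted p = 0.411), and without scrambled array 1 it was -0.40. Genes of cholesterol synthesis and sterol regulation shifted up by +0.28, with 18 of 24 above 0 and 0 past the list-alone threshold, among them ACAT2 (+0.86), NSDHL (+0.56), LSS (+0.52) and LPIN1 (+0.51), and hypoxia and glycolysis genes by +0.22, with 25 of 32 above 0 and 0 past it, with ANKRD37 at +1.14 and PFKFB4 at +0.66. Adjusted p was 0.00828 and 0.034, and 0.949 each with an estimated correlation. The sterol call was lost without scrambled array 1 (+0.17, adjusted p = 0.153), and the hypoxia call without scrambled array 1 (-0.004, 0.975), VEGF-C array 1 (+0.22, 0.0607) or NRP-2 array 2 (+0.17, 0.345), with +0.44 without scrambled array 2. Without NRP-2 array 1 ACAT2 was at +0.52 and NSDHL at +0.36, without NRP-2 array 2 3 sterol members passed as higher, and without scrambled array 1 ANKRD37 was at +0.70 and PFKFB4 at +0.44. S phase genes shifted by +0.95 and G2 and mitosis genes by +1.03, with 33 of 34 and 38 of 38 above 0. Adjusted p of each list was 4.26e-07, and 0.949 with an estimated correlation. In each list 0 members passed the list-alone threshold, with PCNA at +0.94, RFC2 at +0.78 and RFC4 at +0.76. Members of both lists passed as higher with the replicate number as a block, as counted below under the processing alternatives. Without scrambled array 1, 34 G2 and mitosis members passed as higher, and without NRP-2 array 2, 26 S phase members. Without NRP-2 array 1 PCNA was at +0.47, RFC2 at +0.32 and RFC4 at +0.42.

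Over all genes limma called 0 with NRP-2 siRNA (lowest adjusted p 0.138), and 1478 had an unadjusted p under 0.05, 716 higher and 762 lower, against 556.55 expected by chance. Those with the smallest p, not past the threshold over all genes, were TRHDE (+1.78), CREG2 (+1.61), LINC00294 (+1.66), WDFY1 and the scramblase gene PLSCR4 (+1.56) among those higher, and the fatty acid elongase gene ELOVL7 (-1.43), the signalosome subunit COPS4 (-1.47), ZBTB34 (-1.24), ACOXL (-1.53) and the hyaluronan synthase gene HAS2 (-0.95) among those lower. Of the 10 calls made over a list alone, 0 were kept among 35 without scrambled array 1, 3 among 4 without scrambled array 2, 7 among 7 without either VEGF-C array, 2 among 4 without NRP-2 array 1 and 9 among 85 without NRP-2 array 2. The mean of the G2 and mitosis genes differed by 1.00 between the NRP-2 arrays and by 1.62 between the scrambled arrays, and with it as a covariate 4 of the 10 were kept, those of LAMP2, WDFY1, ITGA2 and LAMC1, while NPC1 was lost at -1.14 (SE 0.22 in place of 0.17). The call of ITGA2 was lost without either scrambled array, that of LAMC1 without scrambled array 1 (+1.52, 0.0761) or NRP-2 array 1 (+1.77, 0.0966), that of NPC1 without either scrambled array or NRP-2 array 1, and that of MTMR6 without any 1 of the 4 arrays compared. Those of RRAGD, SEMA3A and COL1A1 were lost without any array but NRP-2 array 2, with COL1A1 at -0.49 (0.0731) without NRP-2 array 1. For the mean of all probe sets the calls of LAMC1 (+0.58, adjusted p = 0.151 over the list alone), MTMR6 (+0.44, 0.198), NPC1 (-0.74, 0.1) and COL1A1 (-0.37, 0.0957) were lost. Those of SEMA3A (0.06) and COL1A1 (0.284) were lost with no low-value filter, and that of RRAGD (0.0774) with arrays shifted to equal medians.

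The autophagy machinery as a whole was not called with either siRNA, which with 2 arrays per group does not exclude a shift. Its 50 measured members had a mean of +0.06 with VEGF-C siRNA and -0.02 with NRP-2 siRNA (adjusted p = 0.461 and 0.843), with 1 member, EPG5, past the list-alone threshold with VEGF-C siRNA and 0 with NRP-2 siRNA, where ATG13 was at -1.36 (-0.66 for the mean of all probe sets) and PIK3R4 at -0.76. The call of EPG5 was lost without scrambled array 1 (+1.24, adjusted p = 0.214 over the list alone), scrambled array 2 (+1.07, 0.385), VEGF-C array 1 (+1.08, 0.187) or VEGF-C array 2 (+1.24, 0.227), for the mean of all probe sets (+0.75, 0.147) and with the covariate (+0.92, SE 0.20, 0.284). CALCOCO2, an autophagy receptor, was at +0.48 with VEGF-C siRNA. The 39 lysosomal proteins had means of -0.09 and -0.04 (adjusted p = 0.122 and 0.317), with ASAH1 at -0.57 and CTSZ at -0.51 with VEGF-C siRNA. The 14 vacuolar ATPase subunits had means of -0.01 and -0.10 (0.853 and 0.219), with 0 members called and ATP6AP2 at -0.41 and -0.32. The 42 endosome trafficking genes had means of +0.02 and -0.02 (0.91 and 0.642), with WDFY1 and MTMR6 risen in both comparisons and VPS39 at -0.57 with NRP-2 siRNA. The 40 mTORC1 signalling components had means of -0.07 and -0.03 (0.722 and 0.797), with TSC1 at -0.90 and SESN3 at +0.91 with NRP-2 siRNA and PRKAA2 at -0.62 with VEGF-C siRNA (-0.39 for the mean of all probe sets). The VEGF, neuropilin, semaphorin and plexin list (19 members) had means of -0.34 and -0.15 (0.412 and 0.503). It holds the targets VEGFC (-3.95 with VEGF-C siRNA) and NRP2 (-1.74 with NRP-2 siRNA), which weigh on these means. Its medians were -0.04 and -0.02.

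Other lists were not called against scrambled siRNA, with means given for VEGF-C siRNA and then for NRP-2 siRNA. Unfolded protein response chaperones (22) had +0.06 and +0.04 (adjusted p = 0.665 and 0.809), with MANF, an endoplasmic reticulum stress protein, at +0.50 and +0.52. The p53 targets (22) had +0.04 and +0.08 (0.809 and 0.955), with the death receptor gene FAS at +1.13 and +1.61 and GDF15 at +0.16 and -1.07. With NRP-2 siRNA GDF15 was at -0.54 for the mean of all probe sets and -0.01 without _x_at probe sets, and FAS was at +1.07 without NRP-2 array 1. Apoptosis regulators (30) had +0.15 and +0.10 (0.164 and 0.765), with CASP8 at -0.51 with NRP-2 siRNA. Adhesion and matrix genes (40) had +0.20 and +0.02 (0.11 and 0.809), with LAMB3 at +1.06 and SNAI2 at +1.31 with VEGF-C siRNA (+0.73 with the covariate). Growth factor genes (28) had +0.06 and -0.06 (0.665 for each), luminal prostate markers (8) had -0.21 and -0.07 (0.665 and 0.91) with TMPRSS2 at -0.55 and -1.57, and RNA interference genes (12) had -0.18 and -0.04 (0.888 and 0.809) with AGO1 at -0.42 and -0.69. With NRP-2 siRNA and the mean of all probe sets TMPRSS2 was at -0.96 and AGO1 at -0.30, and without NRP-2 array 1 TMPRSS2 was at -0.94. Respiratory chain subunits (29) had -0.01 and +0.13 (0.955 and 0.117), and ribosomal proteins (38) had -0.01 and 0.00 (0.955 for each). Sterol genes had -0.16 (0.0704) and hypoxia genes -0.09 (0.91) with VEGF-C siRNA, and inflammatory genes had +0.28 (0.108) and NRF2 genes +0.04 (0.642) with NRP-2 siRNA, where GSR was at -1.99. Endothelial markers with 2 measured members (ROBO4 at +0.46 and +0.51, PECAM1 at -0.86 and -0.01) and leukocyte markers with 1 (LYZ at -0.30 and +0.49) were too few to test. Without scrambled array 1 and without scrambled array 2 ROBO4 was at +0.83 and +0.19 and LYZ at +0.04 and +0.94 with NRP-2 siRNA, and PECAM1 at -1.58 and -0.14 with VEGF-C siRNA. Without NRP-2 array 1 ROBO4 was at +0.31 and LYZ at +1.78, and LYZ was at -0.80 without NRP-2 array 2. The median opposed the mean in the mTORC1 and ribosomal lists with VEGF-C siRNA and in the endosome, p53 and apoptosis lists with NRP-2 siRNA, and between the siRNAs in the endosome and RNA interference lists. The test pointed down with the mean and median above 0 in the ribosomal list with NRP-2 siRNA and in the mTORC1 and p53 lists between the siRNAs.

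The siRNAs against ligand and co-receptor differed from each other in interferon and stress genes, which were lower with NRP-2 siRNA than with VEGF-C siRNA. Over its list alone, 22 of 44 interferon response members were lower and 0 higher, among them XAF1 (-2.65, SE 0.44), TRIM22 (-1.57, SE 0.26), OASL (-1.31, SE 0.14) and IFIT3 (-1.15, SE 0.13), and the list had a mean of -0.64. Of the integrated stress and amino acid response members, 16 of 34 were lower and 0 higher, among them CTH (-2.16, SE 0.37), the transcription factor gene DDIT3 (-1.24, SE 0.28), WARS1 (-1.24, SE 0.25) and PPP1R15A (-1.17, SE 0.18), with a list mean of -0.77. Adjusted p was 4.53e-15 and 4.75e-14, and 0.949 for each with an estimated correlation. The interferon means of the arrays were 10.94 and 11.25 with scrambled siRNA, 11.54 and 11.43 with VEGF-C siRNA, and 10.82 and 10.88 with NRP-2 siRNA. Those of the stress list were 11.80 and 11.68, 12.08 and 12.06, and 11.04 and 11.56. Adjusted over the list alone, 15 interferon members passed as lower without either scrambled array, 2 without VEGF-C array 1, 4 without VEGF-C array 2, 13 without NRP-2 array 1 and 11 without NRP-2 array 2. Of stress members, 2 passed as lower without either scrambled array, 0 without either VEGF-C array, 10 without NRP-2 array 1 and 27 without NRP-2 array 2. With no low-value filter 13 interferon and 15 stress members passed as lower. The mean of the stress list was -0.51 without NRP-2 array 1.

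**Figure D2:**
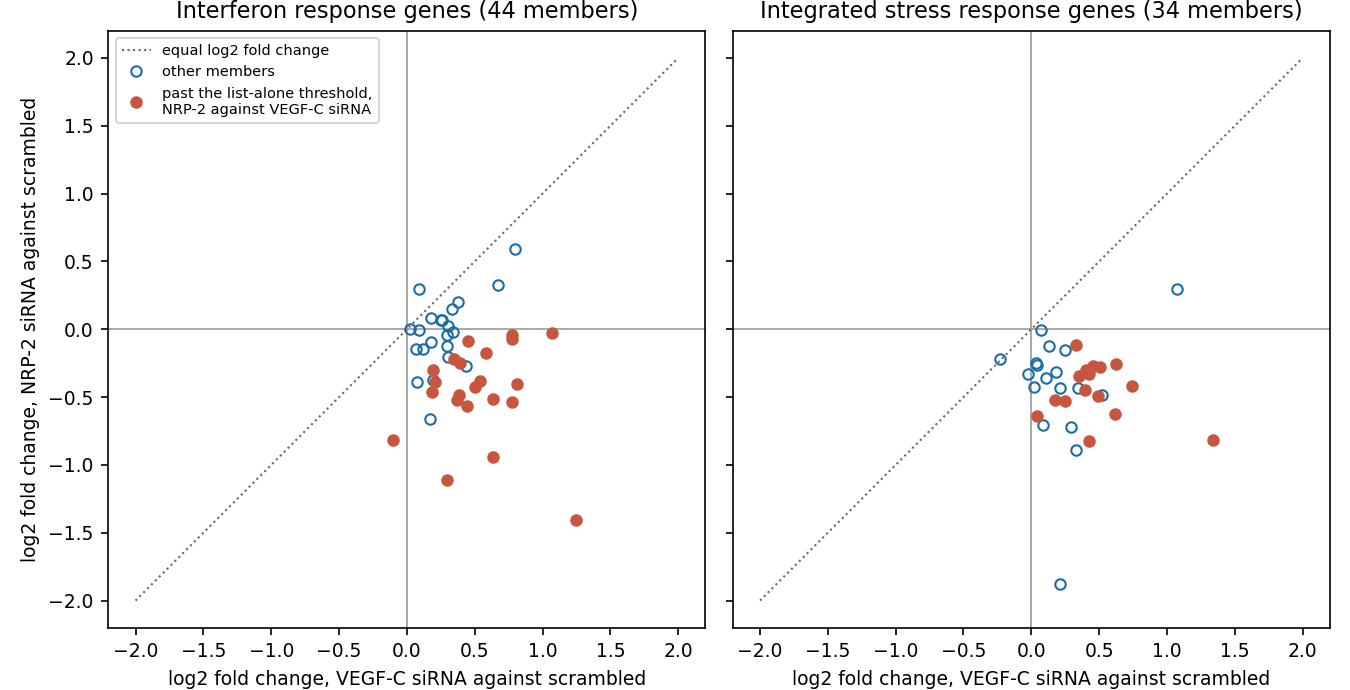
Log2 fold changes of 44 interferon response genes (left) and 34 integrated stress response genes (right) with VEGF-C siRNA (horizontal axis) and NRP-2 siRNA (vertical axis), each against scrambled siRNA, with a point for each gene and a dotted line of equal change. Filled points, 22 on the left and 16 on the right, passed the threshold over their list alone for NRP-2 against VEGF-C siRNA, and they lie below the line.

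Single genes of lysosomal and nutrient lists passed over their list alone between the siRNAs, while those lists were not called. NPC1 (-1.57, SE 0.17, adjusted p = 0.00589 over the list alone) and ATP6V0A2 (-0.98), a vacuolar ATPase subunit, were lower with NRP-2 siRNA, 1 of 39 lysosomal proteins and 1 of 14 vacuolar ATPase subunits (adjusted p of the lists = 0.594 and 0.589). Among the 40 mTORC1 components (0.91), FNIP2 (+1.37), SESN3 (+1.25), SESN1 (+1.04) and LAMTOR4 (+0.85) were higher and SESN2 (-1.23) and RRAGD (-0.83) lower. DICER1 (+1.80), SEMA3E (+1.43), PLXNB1 (+0.90), SEMA3F (+0.81), the p53 targets TP53INP1 (+1.30) and ZMAT3 (+0.68), and CALR (+0.56) were higher. ITGA2 (-1.56), GDF15 (-1.23), AKR1C1 (-1.19), ERN1 (-0.92), a sensor of unfolded proteins, SEMA3A (-0.82), DNAJB9 (-0.81), GADD45B (-0.75) and CDKN2A (-0.48) were lower. For the mean of all probe sets ATP6V0A2 turned to +0.08, GDF15 was at -0.62, and the calls of NPC1 (-0.79, adjusted p = 0.0751 over the list alone), CDKN2A (-0.28), CALR, DNAJB9, SEMA3A, SEMA3F and ZMAT3 were lost. With no low-value filter 49 of the 64 calls between the siRNAs were kept, and outside the interferon and stress lists those of SESN2, SEMA3F, ITGA2, DICER1 and, among mTORC1 components, SESN1 were lost. Calls were lost with arrays shifted to equal medians for CALR, DNAJB9 and ERN1, and with the covariate for CALR, DNAJB9 and CDKN2A. Sterol genes shifted by +0.44 with 21 of 24 above 0, hypoxia and glycolysis genes by +0.30 with 26 of 32 above 0, and NRF2 genes by -0.27 with 18 of 24 below 0 (adjusted p = 2.61e-05, 0.0289 and 0.014, and 0.949 for each with an estimated correlation). The hypoxia call was lost without VEGF-C array 1 (+0.26, adjusted p = 0.245) or NRP-2 array 2 (+0.25, 0.173), and the NRF2 call without NRP-2 array 2 (-0.16, 0.356). The other 18 lists tested were not called, with adjusted p of 0.0553 for S phase genes (+0.44), 0.178 for G2 and mitosis genes (-0.28), 0.116 for inflammatory genes (-0.51) and 0.199 for autophagy machinery (-0.08).

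Over all genes limma called 0 between the siRNAs (lowest adjusted p 0.098), while 2026 had an unadjusted p under 0.05, 1062 higher and 964 lower, against 556.55 expected by chance. Those with the smallest p, not past the threshold, were CREG2 (+2.27), SLC40A1 (+1.45), LDB3 (+1.27), VEGFC (+3.97) and LCOR (+1.36) among those higher, and TLNRD1 (-1.49), NRP2 (-2.65), OASL, NPC1 and IFIT3 among those lower. Of the 64 calls made over a list alone, with SESN1 in 2 lists, 35 were kept among 41 without either scrambled array, 11 among 13 without VEGF-C array 1, 13 among 16 without VEGF-C array 2, 27 among 38 without NRP-2 array 1 and 41 among 75 without NRP-2 array 2. The calls of NRP2, VEGFC, AKR1C1, OASL and IFIT3 were kept without any of the 6 arrays, and those of CALR, CDKN2A, ZMAT3, the stress gene CEBPB and the interferon genes CMPK2, CXCL10, IRF7 and OAS2 were lost without any 1 of them. Those of ATP6V0A2 and SEMA3F were lost without any array but VEGF-C array 1, and those of DNAJB9 and ERN1 without any but NRP-2 array 2. Among mTORC1 components, FNIP2, SESN3 and LAMTOR4 were lost without either VEGF-C array or NRP-2 array 1, SESN1 and SESN2 without any 1 of the 4 arrays compared, and RRAGD without VEGF-C array 2 or either NRP-2 array. GDF15, and SESN1 among p53 targets, were lost without either VEGF-C array or NRP-2 array 1, PLXNB1 without either VEGF-C array or NRP-2 array 2, and ITGA2 without either scrambled or either VEGF-C array. DICER1 was lost without either NRP-2 array, GADD45B and SEMA3A without VEGF-C array 1 or NRP-2 array 1, NPC1 and TP53INP1 without NRP-2 array 1, and SEMA3E without VEGF-C array 1. With the mean of the G2 and mitosis genes as a covariate 58 were kept.

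Changes with the siRNAs against scrambled siRNA were correlated across the 11131 genes, which are not independent replicates. Pearson's r was 0.445 and Spearman's rho 0.394, where simulated unchanged groups against the same controls gave a Pearson's r of 0.50. The covariance was 0.0735 against a simulated 0.0403, a difference of 0.0332, and 64.1% of genes had the same sign against a simulated 66.7%. No gene was called by limma in both comparisons (0). At an unadjusted p under 0.05 in both, 204 genes were higher and 193 lower, where independent lists would share 49.8 and 59.4 and simulated unchanged groups gave 77.85 and 77.75, and 51 genes went opposite ways. The simulated groups held no changed genes. In such groups 556.55 genes would be expected at an unadjusted p under 0.05 in each comparison. Here 1642 and 1478 genes had such a p, so the simulated counts are not on the same footing. How much of the excess comes from the shared controls, which are too few to split, is not known. The correlation was 0.23 without NRP-2 array 1 and 0.61 without scrambled array 1.

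Cell cycle genes differed between arrays of a group as well as between groups. The mean of the 38 G2 and mitosis genes was 10.41 and 8.79 on the scrambled arrays, 11.26 and 10.55 on the VEGF-C arrays, and 11.13 and 10.12 on the NRP-2 arrays. The mean of the 34 S phase genes was 8.90 and 8.50, 9.63 and 8.79, and 10.31 and 8.98. The difference of ACTB probe sets at the 5' and 3' ends of the transcript, a measure of RNA integrity, was -3.11 and -2.05 on the scrambled arrays, -2.11 and -2.28 on the VEGF-C arrays, and -2.18 and -2.76 on the NRP-2 arrays. With VEGF-C siRNA the shift of the G2 and mitosis list was +0.50 without scrambled array 2 and +2.12 without scrambled array 1, and the S phase call was lost without scrambled array 2 (+0.31, adjusted p = 0.131) or VEGF-C array 1 (+0.09, 0.832), with +0.93 without VEGF-C array 2. With NRP-2 siRNA the G2 and mitosis call was lost without scrambled array 2 (+0.22, adjusted p = 0.254), with +1.84 without scrambled array 1 and +0.53 without NRP-2 array 1, and the S phase shift was +0.28 without NRP-2 array 1 and +1.61 without NRP-2 array 2.

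**Figure D3:**
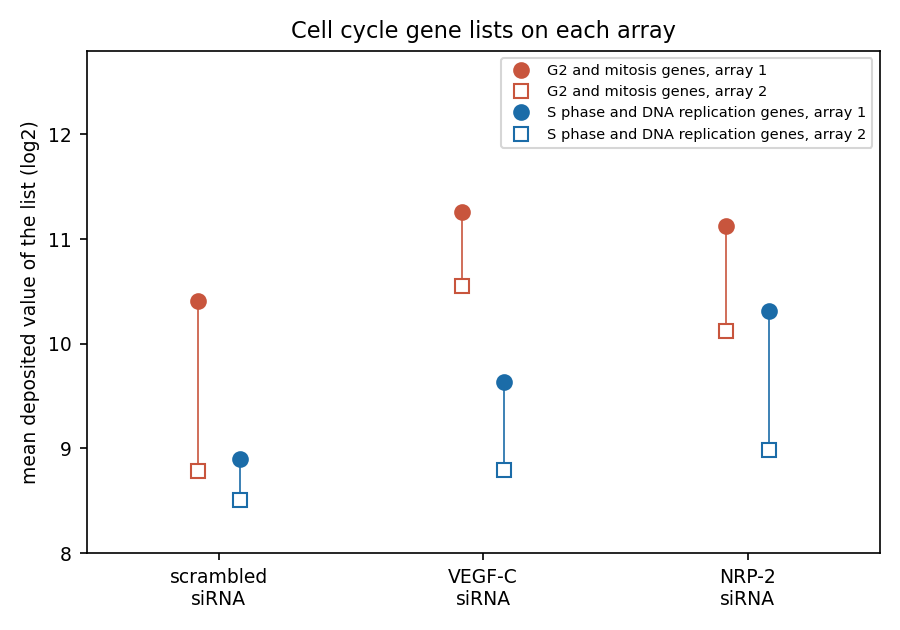
Mean deposited log2 value (vertical axis) of the G2 and mitosis genes and of the S phase and DNA replication genes on each array, by siRNA group (horizontal axis), with a filled circle for array 1, an open square for array 2 and a line joining the arrays of a group. Scrambled array 2 has the lowest G2 and mitosis mean, 8.79, and VEGF-C array 1 the highest, 11.26.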

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

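The tests with the G2 and mitosis mean as a covariate were set before their result was seen, and the tests of single arrays and of the siRNA sequences only afterwards. Among lists with opposite directions against scrambled siRNA, 4 also passed the test of the difference between NRP-2 and VEGF-C siRNA, though each had an adjusted p of 0.949 with an estimated correlation.

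Interferon response genes had a mean of +0.39 with VEGF-C siRNA and -0.24 with NRP-2 siRNA, a difference of -0.64, and integrated stress and amino acid response genes +0.33 and -0.44, a difference of -0.77. The prediction was that a difference in growth state between the cultures would lose most of this under the G2 and mitosis covariate. With it the differences were -0.67 and -0.79. Their 95% intervals over members, which are not independent, ran from -0.83 to -0.51 and from -0.96 to -0.62. This cannot exclude growth state, because the covariate differed little between these groups (10.91 ± 0.50 with VEGF-C siRNA, 10.63 ± 0.71 with NRP-2 siRNA). The S phase means (9.21 and 9.65) were not used as a covariate. No single array carried the interferon difference, which was nearest 0 without VEGF-C array 1 at -0.58 (-0.74 to -0.42), while the stress difference was -0.51 without NRP-2 array 1 with an interval from -0.65 to -0.37, which reaches the bound of -0.38 set for it, so that this array may account for much of it. An innate response to the siRNA sequences themselves cannot be told apart from an effect of the targets, because the interferon difference of -0.64 comes from 1 siRNA group per target and the suppliers differed. A biological difference between depletion of the ligand and of the co-receptor also stays open, as untested.

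Cholesterol and sterol regulated genes had a mean of -0.16 with VEGF-C siRNA and +0.28 with NRP-2 siRNA, a difference of +0.44 (adjusted p = 2.61e-05, 21 of 24 members above 0), and the NRP-2 mean was +0.17 (adjusted p = 0.153) without scrambled array 1. Hypoxia and glycolysis genes had -0.09 and +0.22, a difference of +0.30 (adjusted p = 0.0289, 26 of 32 members above 0). Without scrambled array 1 the NRP-2 mean was -0.004, so the opposite directions were lost, and the difference lost its call without VEGF-C array 1 (+0.26, 0.245) or NRP-2 array 2 (+0.25, 0.173).

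Among 2932 probe sets without 1 gene name, outside the comparisons of genes, limma called 1 between NRP-2 and scrambled siRNA (lowest adjusted p 0.0491) and 4 between NRP-2 and VEGF-C siRNA (lowest adjusted p 0.02), against 0 between VEGF-C and scrambled siRNA (0.221). Unadjusted p was under 0.05 for 387, 481 and 356 of them in these 3 comparisons.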

How the results depend on the processing

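The G2 and mitosis covariate, and alternatives for the correlation and for members past the list-alone threshold, were chosen after seeing the data. With an array left out, the lone array of its group is assumed to vary like the other groups. The number of genes called by limma, 0 in each comparison, became 1 with no low-value filter for VEGF-C against scrambled siRNA (lowest adjusted p 0.0439) and for NRP-2 against VEGF-C siRNA (0.0374), and 1 for the latter with the filter on the highest group mean (0.0404), where the cause was not tested. By looser thresholds it was 54 at adjusted p under 0.1 for NRP-2 against VEGF-C siRNA, and 198, 245 and 335 in the 3 comparisons at an unadjusted p under 0.05 with at least a 2-fold change. It stayed 0 under the other alternatives, each array left out included, and over the alternatives the lowest adjusted p ran from 0.0439 to 0.813, 0.0555 to 0.734 and 0.0374 to 0.289. The 6, 6 and 5 lists called by camera became 0, 0 and 0 with an estimated inter-gene correlation, which was above the preset 0.01 in each of them, and 0, 0 and 0 with fry. That correlation ran from 0.0562 for NRF2 genes to 0.973 for G2 and mitosis genes. It was 0.826 for S phase, 0.553 for stress and 0.415 for interferon genes. The preset takes members as nearly independent, so camera's p-values with it may be far too small for such lists. Between the siRNAs, leaving out an array gave 5 to 9 lists, with 9 without NRP-2 array 1, where the cause was not tested. The correlation of the changes ran from 0.23 without NRP-2 array 1 to 0.61 without scrambled array 1, and these arrays weigh on it directly.

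The targeted genes kept their direction under every alternative that gave a value, VEGFC from -4.54 to -3.35 and NRP2 from -2.04 to -1.44. NRP2 has no value with the filter at log2 5, and the G2 and mitosis list none with its own mean as a covariate. Of 2487 alternative values for 125 results over 115 named genes, 6 reversed. Outside these 125, ATP6V0A2, past the threshold over its list alone between the siRNAs, reversed to +0.08 for the mean of all probe sets. STAM2 was +0.033 and COX4I1 -0.13 with NRP-2 siRNA for the mean of all probe sets, CFLAR -0.30 with VEGF-C siRNA without _x_at probe sets, and PECAM1 +0.44 with VEGF-C siRNA with the covariate. With NRP-2 siRNA and an array left out, COL3A1 ran from -0.044 to +0.76 and LYZ from -0.80 to +1.78. The S phase list with VEGF-C siRNA reversed to -0.30 with the covariate. The cause of these was not tested. Of 219 alternative values for the 17 called lists, 172 kept direction and call, 46 lost the call and 1 reversed.

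The labels give each group the same replicate numbers, but with 2 numbers a pairing is not established, and the array differences of the groups correlated at 0.112, 0.579 and 0.119 across genes. With the replicate block limma called 0 genes in each comparison and 7, 6 and 7 lists, and 16 of 18, 9 of 10 and 57 of 64 calls over a list alone were kept, among 72, 77 and 77 then made. They included 38 G2 and mitosis and 4 S phase members higher with VEGF-C siRNA, and 35 and 23 with NRP-2 siRNA, where 0 had passed. The calls lost were those of NRP2 and PLXNA2 (adjusted p = 0.0783 over the list alone for each) with VEGF-C siRNA, SEMA3A (0.0661) with NRP-2 siRNA, and CALR, DNAJB9, CMPK2, IRF7, OAS2, RIGI and SAMD9L between the siRNAs. Each siRNA array lay above the scrambled array of its number in the G2 and mitosis mean (11.26 and 11.13 over 10.41, 10.55 and 10.12 over 8.79) and in the S phase mean (9.63 and 10.31 over 8.90, 8.79 and 8.98 over 8.50).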

Other observations

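Of the genes with an unadjusted p under 0.05 in both comparisons against scrambled siRNA, none of which passed over all genes, several with larger changes were picked after their values were seen. The protocadherin genes PCDHB7 (-1.68 with VEGF-C siRNA, -1.58 with NRP-2 siRNA) and PCDHB14 (-1.48, -1.44) were lower with both, as were the tyrosine kinase gene FRK (-1.53, -1.60), the neuropeptide gene NTS (-1.35, -1.48) and the adhesion gene CXADR (-0.99, -1.62). The kinase gene DYRK2 (+1.53, +1.39), P2RX7, an ATP-gated channel (+1.49, +1.43), the nuclear lamina gene LMNB1 (+1.31, +1.89), the repressor E2F7 (+1.27, +1.11) and the secreted STC1 (+1.07, +2.03) were higher with both. The comparisons share the scrambled arrays.

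Some growth factor, metabolic and luminal genes named by the rule for lists had not passed over their list alone. HBEGF, a ligand of the EGF receptor, was at +1.06 with VEGF-C siRNA and -0.41 with NRP-2 siRNA, and IGF2R at -0.17 and -0.56. PDK3, a kinase that restrains pyruvate dehydrogenase, was at -1.81 and +0.09, and ADM, a hypoxia-induced peptide hormone, at +0.60 and +0.13. The glucocorticoid and androgen target FKBP5 was at +0.44 and +1.06, SLC45A3 at -0.97 and -0.23, and KLK3 at +0.48 and -0.03. With VEGF-C siRNA PDK3 was at -1.15 for the mean of all probe sets, and without scrambled array 2 HBEGF was at +0.68 and SLC45A3 at -0.62. With VEGF-C siRNA and the G2 and mitosis mean as a covariate HBEGF was at +0.50 and SLC45A3 at -0.41.

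The test of 2-fold changes above a LAMP2 signal ceiling was set before its result was seen, and the other tests below only afterwards. G2 and mitosis genes had higher means on array 1 than on array 2 in each group, by 1.62, 0.71 and 1.00 for scrambled, VEGF-C and NRP-2 siRNA. The ACTB 5' to 3' difference between the arrays went both ways (-1.06, +0.16 and +0.58, a range of 1.63), unlike the G2 and mitosis difference. That of GAPDH hardly moved (-0.08, +0.03 and -0.04). The test of RNA integrity asked for the same pattern in both genes and could not decide, so loss of RNA integrity stays open. A growth state that goes with the array number may apply, but chance alone gives a common direction in 3 groups with probability 0.25. A response to the siRNAs may add to it, as the 4 siRNA arrays had a mean 1.17 above the 2 scrambled arrays and each lay above the scrambled array of its number, with an exact permutation p of 0.2 over 15 splits that ignore the numbers and allow 0.0667 at the smallest.

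The brightest LAMP2 probe set changed with the siRNAs and the dimmest was at +0.02 with VEGF-C siRNA and +1.89 with NRP-2 siRNA, while 2 others hardly changed. A signal ceiling common to the array at their level (log2 12.89 for the higher) is excluded, since 547 tested genes lay above the highest value of the 2 (13.14) on each of the 6 arrays, and the brightest probe set itself rose from 12.39 to 13.89. The test set beforehand was undecided by itself, with 6 of 843 genes above that level at least 2-fold different at an unadjusted p under 0.05 between NRP-2 and scrambled siRNA, where 0 would have fitted a ceiling and 10 would have spoken against it, and saturation particular to the 2 probe sets was not tested. A candidate explanation is an unequal change of LAMP2 transcript forms. The annotation names a different target sequence for each LAMP2 probe set, and which forms they measure was not tested. The brightest minus the mean of the 2 others was 1.18 higher on the 4 siRNA arrays than on the 2 scrambled arrays. It was -0.38 and 0.05 with scrambled, 0.91 and 0.69 with VEGF-C, and 1.24 and 1.21 with NRP-2 siRNA. The exact permutation p was 0.0667, the smallest that 15 splits allow. These probe sets were picked on the same arrays for this pattern, so the p restates it and the explanation stays open. The dimmest probe set was not in this test.

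NRP-2 array 2 was closer to each scrambled array than to the other array of its own group. The standard deviation of the difference over tested genes was 0.397 to scrambled array 1 and 0.339 to scrambled array 2, against 0.472 to NRP-2 array 1. Between the scrambled arrays it was also 0.339. Pearson's r across all probe sets was 0.9964 and 0.9974 to the scrambled arrays, against 0.9956 to NRP-2 array 1. This limits every comparison with NRP-2 siRNA. NRP2 stood at log2 2.81 on NRP-2 array 2, against 3.41 on NRP-2 array 1 and 4.92 on scrambled array 2. The first principal component held 41.0% of the variance and the second 32.5%.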
